A study of Mus musculus with 16 samples.

How the data were processed

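Brains of 8 young mice (2 to 3 months of age, per the labels) and 8 old mice (21 to 22 months, per the labels) were dissociated, and each brain gave 1 single-cell RNA-seq library. Per the labels' protocols, the libraries were made with a droplet kit (Chromium, 10x Genomics) that reads the 3' end of each transcript and marks each captured molecule with a unique molecular identifier (UMI). Read counts are therefore counts of molecules, and copies made by PCR do not inflate them. Per the submitters' processing notes, Cell Ranger 1.2, Seurat 2.3 and R 3.3.4 were used. The notes name the genome builds mm10 and mm9 without their roles. The aligner settings, the gene annotation, the filters on cells and genes and the handling of doublets are not given in the sources used here. No doublet caller was run here.

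Each sample had a table of 14699 genes by cells. The deposited values were natural log values, ln(1 + 10000 × UMIs of the gene / total UMIs of the cell). This unit was checked on the values: with the total UMIs per cell from the authors' cell table, 100% of the non-zero values gave a whole number of UMIs within 0.01. The tables held 37069 cells, 16028 young and 21041 old, as many as the sample labels add up to. The series text states 50212 raw and 37089 processed cells. Cell types were the authors' deposited annotation of 25 types, so a difference in how cells of the 2 ages were assigned would enter the values. The files give the types as abbreviations, which were read as the usual names of brain cell types. Genes were taken by the symbols in the files. Coordinates were not used here. Genes with near-identical copies or pseudogenes (ribosomal proteins, MHC class I genes of the H2 family, C4b and C4a, Hba-a1 and Hba-a2, Hspa1a and Hspa1b, PISD) are uncertain, because the treatment of reads matching several genes is not given in the sources used here.

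The depth was 4187394 to 15222665 UMIs per animal over 1370 to 3984 cells. The medians over all cells were 2670 UMIs and 1325 genes, and the lowest cell had 730 UMIs and 309 genes. Total UMIs of young animals 1 to 8 were 4587702, 5071400, 5176775, 6472274, 6091040, 6813764, 7446624 and 8557477. Those of old animals 1 to 8 were 6149161, 4187394, 13720948, 15222665, 6784990, 7760454, 6119302 and 7183572. At this depth a gene of 0.1 transcripts per 10000 is seen in few cells of 1 animal, so low genes and types with few cells have a large counting error.

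The animal was the replicate. The deposited values were turned back to linear values per 10000 UMIs (CP10k) and averaged over the cells of each animal and type. Animals with at least 20 cells of a type and genes with a mean of at least 0.1 CP10k entered its test. Old and young animals were compared on log2(mean CP10k + 0.1) with limma 3.58.1 in R 4.3.3 (linear model, moderated variances with a trend, two-sided), and p-values were adjusted by the Benjamini-Hochberg method within each type, with a threshold of 0.05. Changes on this scale understate the change of low genes. The 6 types with the highest median number of cells per animal were compared in full: oligodendrocytes, astrocytes, mature neurons, microglia, oligodendrocyte precursors and endothelial cells. Olfactory ensheathing glia and pericytes also had enough cells. For each gene the number of old animals in its direction is the number lying on that side of the young mean.

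Gene lists (32, covering cell states and markers of the other cell types of the brain) were tested in each type with at least 5 tested members by limma's camera with a preset correlation of 0.01. Adjustment was over all 153 pairs of list and type. Camera with an estimated correlation and fry stood beside it. Fry tests whether the members move one way on balance and does not compare them with other genes. Shares of cell types, UMIs and genes per cell, and list scores were compared by exact two-sided permutation tests over all 12870 splits of 8 against 8 animals, whose smallest p is 0.0001554, with Benjamini-Hochberg adjustment over 25 shares, 12 depth comparisons and 30 list differences. A list difference is an animal's mean log2 value of the list in 1 type minus its mean over the other 5. The same difference was tested gene by gene with limma on the 5224 genes tested in all 6 types. The exact tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

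The genes named were chosen by a rule. In each of the 6 types it took, among called genes with a mean of at least 0.5 CP10k, the 8 largest changes in each direction, then up to 3 members with the smallest p of each called list, then the genes called in most types. In other types it took the 3 largest in each direction. Gene models without a name were passed over. Some results that the rule selected are not reported here. This rule, the lists, the groups, the tests and the first set of alternatives were fixed before the data were examined. The alternatives were pseudocounts of 1 and 0.02, no filter or a filter at 0.5 CP10k, at least 50 cells, means of the deposited log values, summed UMIs, centring on the median gene, weights by the number of cells, the animal number as a block, genes per cell as a covariate, centred log ratios of cell numbers, shares without the most frequent type, and means in place of medians for depth. Alternatives chosen after seeing the data were neighbouring animal numbers as a random effect or as means, old animals 7 and 8, 5 to 8, or 1 and 2 left out, and each animal left out in turn.

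To place 1 animal between the ages, the 100 genes with the smallest p were chosen without it, and its median position on them was computed, with 0 at the young mean and 1 at the old mean. The gene test was tested on simulated data made from the real means and spread, with 200 genes changed. At a fold of 2 it recovered 98% of them in oligodendrocytes, 90% in mature neurons, 84% in astrocytes, 74% in microglia, 67% in endothelial cells, 37% in oligodendrocyte precursors, 36% in pericytes and 17% in olfactory ensheathing glia. At a fold of 1.5 it recovered 76%, 52%, 57%, 42%, 16%, 11%, 10% and 7%, in the same order. False calls made up 0% (microglia) to 14.3% (olfactory ensheathing glia) of the calls. The simulated animals were independent, so the related deviations of animals with neighbouring numbers in the real data were left out. These rates hold only for independent animals.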

Results

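Single-cell transcriptomes of whole dissociated brains from 8 young and 8 old mice were compared to ask which cell types and which genes within them differ with age. The annotated cells numbered 1370 to 3984 per animal, and the median depth per animal ran from 2029 to 3368 UMIs per cell. Oligodendrocytes were the most frequent type (12384 cells), followed by astrocytes (6747), mature neurons (5135), microglia (3910), endothelial cells (2413) and oligodendrocyte precursors (2187). Levels are means over the cells of an animal in transcripts per 10000 UMIs (CP10k), given as mean ± SD over animals, and log2 changes are old minus young with their SE.

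The animal labelled young 1 lay with the old animals in its expression. On a scale with the young mean at 0 and the old mean at 1, its position was 0.934 in oligodendrocytes, 0.998 in microglia and 0.876 in endothelial cells. The highest of the other 7 young animals reached 0.0408, 0.341 and 0.275 there, and the old animals spanned 0.756 to 1.07, 0.678 to 1.01 and 0.731 to 0.945. In mature neurons, astrocytes and oligodendrocyte precursors its position was 0.974, 0.70 and 0.601, against highest values of 0.507, 0.329 and 0.173 in the other young animals. Its label was kept in every comparison, and values without it are given beside the counts of called genes.

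**Figure D1:**
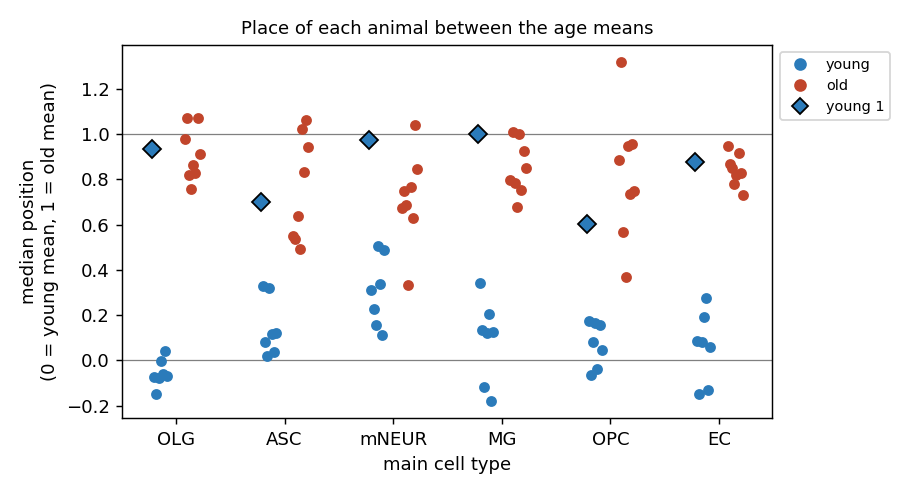
Position of each animal between the age means (vertical axis, median over 100 genes chosen without that animal, 0 = young mean, 1 = old mean) in the 6 cell types with the most cells (horizontal axis: OLG oligodendrocytes, ASC astrocytes, mNEUR mature neurons, MG microglia, OPC oligodendrocyte precursors, EC endothelial cells). Points are animals, and the black-edged diamond is the animal labelled young 1, which lies at 0.601 to 0.998.

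Libraries also differed within the ages. Old animals 7 and 8 had the fewest UMIs per cell (2039 and 2029), and old animals 5, 7 and 8 had the highest share of UMIs from Malat1, a nuclear noncoding RNA (5.40%, 7.87% and 5.54%, against 3.46% to 4.54% in the others). Numbers carried in the cell names ran from 6 to 28 in the young and from 33 to 44 in the old animals, so a library series and age cannot be told apart. Animals of 1 age with neighbouring numbers deviated together: across 2823 genes in oligodendrocytes, the mean correlation of their deviations was 0.255, against -0.196 for other pairs of the same age. Treating neighbours as related lowered the counts of called genes to 169 in oligodendrocytes, 40 in endothelial cells, 39 in microglia, 32 in oligodendrocyte precursors, 16 in astrocytes and 0 in mature neurons.

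Oligodendrocyte precursors and 2 types of the neuronal lineage made up a smaller part of the cells in old brains. Oligodendrocyte precursors, the proliferating cells that give rise to oligodendrocytes, fell from 7.11% ± 0.899 of annotated cells to 4.63% ± 1.30 (SD, n = 8 and 8; exact permutation p = 0.000466, adjusted p = 0.00583; lower in 8 of 8 old animals). Immature neurons fell from 0.809% ± 0.386 to 0.146% ± 0.104 (exact permutation adjusted p = 0.00583; 8 of 8) and neuronal-restricted precursors from 0.374% ± 0.156 to 0.108% ± 0.122 (exact permutation adjusted p = 0.0220; 8 of 8). The last 2 types rest on 162 and 82 cells in all. None of the other 22 types passed. The nearest were macrophages, with -0.32 percentage points, and neural stem cells, with -0.294 (exact permutation adjusted p = 0.0559 for both; 7 and 8 of 8 old animals). Astrocytes made up 20.1% ± 5.05 and 16.0% ± 2.66 of cells (adjusted p = 0.218).

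The call for oligodendrocyte precursors was lost on centred log ratios of the cell numbers (-0.26; adjusted p = 0.245), and that for neuronal-restricted precursors without old animals 7 and 8 (adjusted p = 0.0888) or 1 and 2 (0.0791). The animal labelled young 1 had 5.40% oligodendrocyte precursors and 0.219% immature neurons, below the 6.72% to 8.30% and 0.596% to 1.56% of the other young animals. Without it, astrocytes (-5.68 points, adjusted p = 0.0140) and neural stem cells (-0.35, 0.00388) also passed, and without old animal 6 macrophages (-0.387, 0.00518) and vascular smooth muscle cells (0.403, 0.0420) did. These shares describe dissociated cells that passed the authors' filters.

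**Figure D2:**
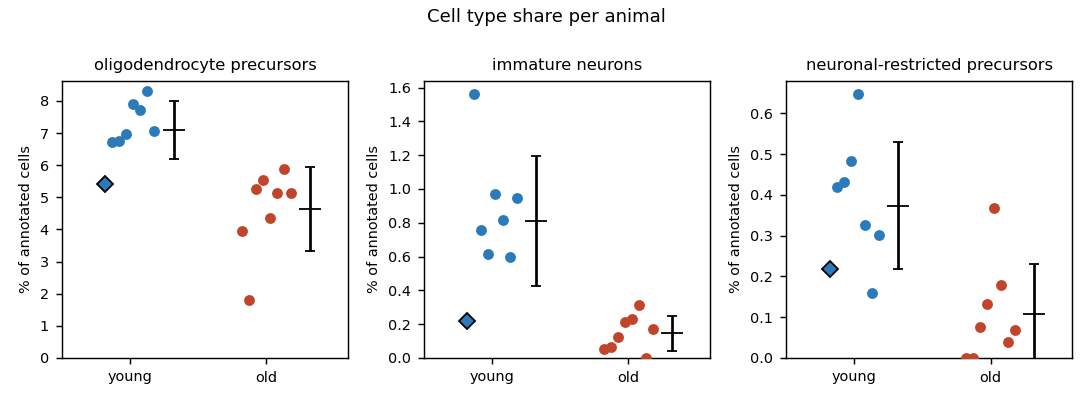
Share of annotated cells (vertical axis, percent) of oligodendrocyte precursors, immature neurons and neuronal-restricted precursors in each young (blue) and old (red) animal, with mean ± SD at the side (the axis starts at 0). The black-edged diamond, the animal labelled young 1, lies at 5.40%, 0.219% and 0.219%.

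Depth did not separate the ages by the exact test: 0 of 12 comparisons of UMIs or genes per cell passed, and the largest difference was in microglia, with 2268 ± 272 UMIs per cell in young and 2698 ± 498 in old animals (difference 430.0, exact permutation p = 0.0527, adjusted p = 0.516, higher in 6 of 8). At an unadjusted p under 0.05 the count was also 0. Without old animals 7 and 8 microglial UMIs (685.3 more per cell) and genes (211.1 more) passed (adjusted p = 0.004 for both).

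In old oligodendrocytes, complement component C4b rose from 0.252 ± 0.328 to 1.36 ± 0.345 CP10k (SD, n = 8 and 8; log2 change 2.33 ± 0.27, adjusted p = 0.000106). C4b was 1.06 CP10k in the animal labelled young 1, within the old range. The MHC class I gene H2-D1 rose from 0.593 ± 0.283 to 1.16 ± 0.362 and the lipid transporter gene Abca8a from 0.529 ± 0.15 to 0.942 ± 0.0607 (log2 changes 0.91 and 0.76; adjusted p = 0.00632 and 0.000155). Mog, a protein of the outer myelin surface, fell from 19.5 ± 1.85 to 14.1 ± 1.16 (-0.47 ± 0.07, adjusted p = 0.000281). Other decreases were in the linker histone gene Hist1h1c (-1.22), the zinc transporter gene Tmem163 (-0.89), Ttyh1 (-0.88), Marcksl1 (-0.85) and the actin-severing protein gene Gsn (-0.69), with adjusted p from 0.000155 to 0.00288. Each of these genes lay on the same side of the young mean in 8 of 8 old animals, and each passed with any 1 animal left out.

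In all, 363 of 7236 genes passed in oligodendrocytes, 148 higher and 215 lower in old animals (1531 at an unadjusted p under 0.05), with a median absolute log2 change of 0.35. Without the animal labelled young 1 the count was 662 and without young 4 it was 228. Without old animals 5 to 8 it was 114, and 16 of the 28 called genes named by the rule kept their calls. Means of the deposited log values called 241 genes, 52 of them higher (21.6% against 40.8%), and summed UMIs called 689.

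Of 22 cholesterol synthesis genes, 21 had a negative change in oligodendrocytes. In this list 7 fell over all genes and 12 adjusted over the list alone, among them Hmgcs1 (2.11 ± 0.373 to 1.18 ± 0.41 CP10k, log2 change -0.86) and Idi1 (-0.46), which encode enzymes of early steps of the pathway (list adjusted p = 1.39e-09, and adjusted p = 0.125 with an estimated correlation). Of 23 genes of myelin and mature oligodendrocytes, called lower as a list, 17 had a negative and 6 a positive change. Over all genes 8 fell, and adjusted over the list alone 9 fell and 4 rose (adjusted p = 0.000389, and adjusted p = 0.212 with an estimated correlation). Besides Mog, these included Fa2h (5.54 ± 0.298 to 4.21 ± 0.43, -0.39), which makes hydroxylated myelin lipids, and the tight junction gene Cldn11 (-0.41).

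Clock genes moved up in oligodendrocytes, with 3 of 11 members higher over all genes and 4 adjusted over the list alone (adjusted p = 0.000364, and adjusted p = 0.125 with an estimated correlation). The repressor Bhlhe41 rose by 0.85 on the log2 scale, Tef by 0.36 and Clock by 0.29. Tef and Clock lost their calls with neighbouring numbers treated as related (adjusted p = 0.0615 and 0.0656), without old animals 5 to 8 (0.179 and 0.138) and on means of the deposited log values. Clock also lost its call without old animals 7 and 8 (0.0737) and with genes per cell as a covariate. Ribosomal protein genes were higher as a group (69 of 79 positive, median log2 change 0.14; 4 higher over all genes, 7 adjusted over the list alone; adjusted p = 1.42e-10, and adjusted p = 0.362 with an estimated correlation). The 4 were Rpl6 (0.91), Rpl5 (0.34), Rps3a1 (0.24) and Rps27 (0.58), the last named after its values were seen. The calls of Rpl6, Rpl5 and Rps3a1 were lost without old animals 5 to 8 (adjusted p = 0.113, 0.0581 and 0.0532), those of Rpl5 and Rps3a1 also on means of the deposited log values, and that of Rps3a1 without any of young 2, 3, 4, 7 and 8 and old 1, 3 and 5 (0.0515 to 0.0726). Nuclear genes of oxidative phosphorylation were lower, with 63 of 77 negative, a median of -0.07 and 0 called over all genes or adjusted over the list alone (adjusted p = 0.000184, and adjusted p = 0.376 with an estimated correlation).

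Markers of other cells moved as well in oligodendrocytes. The list of red blood cell genes was called higher (5 of 6 positive, median log2 change 1.12; 1 over all genes, 1 adjusted over the list alone; adjusted p = 0.00414, and adjusted p = 0.297 with an estimated correlation), but its median turned negative (-0.0045) on means of the deposited log values. Its member Hba-a1, not called over all genes, had a change of 1.46 ± 0.61 (adjusted p = 0.16, higher in 5 of 8 old animals). Astrocyte genes were called lower (17 of 21 negative, 0 called by either count; adjusted p = 0.0165, and adjusted p = 0.589 with an estimated correlation). That call was lost without young 8 (0.158), old 5 (0.0532) or old 6 (0.0942). Heat shock genes (20 of 21 positive, adjusted p = 0.00329, and adjusted p = 0.499 with an estimated correlation) and unfolded protein response genes (15 of 17 positive, adjusted p = 0.0225, and adjusted p = 0.522 with an estimated correlation) had 0 called members by either count. Without old animals 1 and 2 both were lost (0.879 and 0.503). Heat shock was lost without old 1 (0.0666), and unfolded protein response without young 1 (0.0923), young 2 (0.0568), young 6 (0.0979), old 1 (0.104) or old 2 (0.094).

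In old microglia, the resident macrophages of the brain, the secreted glycoprotein gene Spp1 (osteopontin) rose from 0.0668 ± 0.121 to 1.31 ± 0.839 CP10k (SD, n = 8 and 8; log2 change 2.99 ± 0.36, adjusted p = 7.11e-05). Cst7, a cystatin, rose from 0.303 ± 0.243 to 1.00 ± 0.279 (1.58, adjusted p = 0.000599), the cytokine receptor gene Crlf2 from 0.998 ± 0.838 to 2.74 ± 0.381 (1.61, 0.000599) and the interferon-induced gene Ifi27l2a from 0.395 ± 0.232 to 1.23 ± 0.417 (1.52, 0.000775). Lyz2, which encodes lysozyme, rose by 0.91 and Lsp1 by 1.05, but Lyz2 lost its call on summed UMIs. The largest decreases among genes that passed with any 1 animal left out were in Klhdc8b (-0.77), Gp9 (-0.71) and the phospholipase gene Pld1 (-0.69; 1.77 ± 0.369 to 1.09 ± 0.293). All lay on the same side of the young mean in 8 of 8 old animals. In the animal labelled young 1, Spp1 and Crlf2 were the highest of the young values.

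In all, 63 of 7413 genes passed in microglia, 47 higher and 16 lower (927 at an unadjusted p under 0.05). Without the animal labelled young 1 the count was 199. It was 37, 38 and 32 without young 4, 5 and 7, and 41 and 38 without old 7 and 8. Without old animals 5 to 8 it was 11, and 7 of the 28 named called genes kept their calls, among them Spp1, Cst7, Crlf2, Ifi27l2a and H2-D1. The share of higher genes was 74.6%, 89.2% on means of the deposited log values (65 called) and 60.8% on summed UMIs (51 called). With genes per cell as a covariate it was 50.9% (59 called, 39 of them shared with the 63).

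Genes of the disease-associated microglial signature rose as a group: 20 of 22 were positive, 8 rose over all genes and 14 adjusted over the list alone (median log2 change 0.34, adjusted p = 2.57e-18, and adjusted p = 0.0628 with an estimated correlation). Besides Spp1, Cst7 and Lyz2 these included the tetraspanin gene Cd63 (7.16 ± 1.54 to 10.3 ± 1.09, 0.53). Homeostatic microglial genes moved down (17 of 18 negative, median -0.24; 2 fell over all genes and 12 adjusted over the list alone; adjusted p = 7.41e-09, and adjusted p = 0.125 with an estimated correlation). The 2 were the purine receptor gene P2ry12 (39.2 ± 4.87 to 28.5 ± 5.98, -0.48) and Csf1r (27.7 ± 3.92 to 19.5 ± 4.89, -0.53), the receptor on which microglial survival depends. P2ry12 lost its call without any of young 3, 4 and 7 and old 1, 2, 7 and 8 (adjusted p = 0.0527 to 0.0679), and Csf1r without any of young 3 to 8 and old 1, 2, 5, 7 and 8 (0.0532 to 0.0998).

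In old microglia interferon response genes were positive in 13 of 15, with 3 higher over all genes (Ifi27l2a, Ifitm3 at 0.84 and Bst2 at 0.40) and 6 adjusted over the list alone (adjusted p = 1.85e-09, and adjusted p = 0.0587 with an estimated correlation). Ifitm3 and Bst2 lost their calls on summed UMIs, and Bst2 also without old animals 7 and 8 (0.0669) or 5 to 8 (0.123). Of 17 genes of MHC class I and antigen presentation, 3 rose over all genes and 6 adjusted over the list alone (adjusted p = 5.94e-05, and adjusted p = 0.063 with an estimated correlation): H2-D1 (6.83 ± 1.07 to 10.1 ± 1.16, 0.56), B2m (0.38), which encodes the light chain of class I molecules, and H2-K1 (0.50), lost without young 7 (0.0533). With genes per cell as a covariate B2m and H2-K1 lost their calls. Of 14 cytokine and chemokine genes, the chemokine genes Ccl4 (0.72) and Ccl3 (0.63) rose over all genes and 4 adjusted over the list alone (adjusted p = 2.5e-05, and adjusted p = 0.125 with an estimated correlation). Ccl3 was lost without any of young 2, 3, 4, 5, 7 and 8 and old 4 to 8 (0.0563 to 0.107). The list of reactive astrocyte genes was also called higher (8 of 11 positive; 1 over all genes, 3 adjusted over the list alone; adjusted p = 0.00288, and adjusted p = 0.125 with an estimated correlation), and its called member was H2-D1, which many cell types express.

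Ribosomal protein genes were higher in microglia (77 of 80 positive, median log2 change 0.29; 2 over all genes, 61 adjusted over the list alone; adjusted p = 2.57e-38, and adjusted p = 0.155 with an estimated correlation). The 2 were Rpl6 (1.09, 2.68 ± 0.877 to 6.04 ± 2.32), lost without old animals 5 to 8 (0.208), and Rpl23a (0.886 ± 0.397 to 2.55 ± 1.63), lost without any of young 4 to 7 and old 5 to 8 (0.0535 to 0.0783). Mitochondrially encoded transcripts were lower (12 of 13 negative, median -0.40; 2 over all genes, 8 adjusted over the list alone; adjusted p = 1.6e-07, and adjusted p = 0.227 with an estimated correlation). The 2 were mt-Nd1 (62.4 ± 13 to 42.8 ± 3.04, -0.52) and mt-Nd4 (-0.49), lost without young 4 or 7 or any of old 5 to 8 (0.0514 to 0.0694). Heat shock genes were called higher (20 of 23 positive; 0 over all genes, 2 adjusted over the list alone; adjusted p = 0.000141, and adjusted p = 0.372 with an estimated correlation), and lost without old animals 1 and 2 (0.795).

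Of the markers of other cells, 3 lists were called lower in old microglia, while those of myelin (adjusted p = 0.941), oligodendrocyte precursor (0.214) and blood-brain barrier genes (0.432) were not called. Astrocyte genes were negative in 21 of 22, with 0 called over all genes and 10 adjusted over the list alone (median -0.41; adjusted p = 2.13e-08, and adjusted p = 0.285 with an estimated correlation). Neuronal genes were negative in 11 of 14, with 0 and 3 called (adjusted p = 0.0225, and adjusted p = 0.372 with an estimated correlation), and lost without young 4 (0.0583), young 8 (0.0563), old 2 (0.0844) or old 5 (0.0776). Red blood cell genes were negative in 4 of 5 with 0 called (adjusted p = 0.0441, and adjusted p = 0.476 with an estimated correlation), and lost without young 3 (0.166), old 4 (0.0579), 5 (0.0748), 6 (0.0629) or 8 (0.0542).

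In old endothelial cells, which line the vessels of the brain, the immediate early transcription factor gene Fos rose from 0.85 ± 0.245 to 2.20 ± 0.846 CP10k (SD, n = 8 and 8; log2 change 1.24 ± 0.18, adjusted p = 0.00023) and Junb from 1.87 ± 0.555 to 3.20 ± 0.44 (0.78, adjusted p = 0.00432). Stmn2, a regulator of microtubules best known in neurons, rose from 1.2 ± 0.638 to 3.17 ± 0.579 (1.44, 4.92e-05), and Lypd1 from 0.496 ± 0.189 to 1.16 ± 0.26 (1.12, 0.000626). The matrix gene Mgp rose by 1.01 and Gkn3 by 1.36. Sparc, a secreted matrix protein, fell from 16.4 ± 2.47 to 10.5 ± 1.07 (-0.62, 0.00076), Ivns1abp from 1.38 ± 0.429 to 0.53 ± 0.137 (-1.19, 0.000626) and the monocarboxylate transporter gene Slc16a4 from 1.67 ± 0.179 to 1.01 ± 0.273 (-0.71, 0.0134). All lay on the same side of the young mean in 8 of 8 old animals and passed with any 1 animal left out. Sparc and Ivns1abp were lowest, among young animals, in the one labelled young 1.

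In all, 61 of 8324 genes passed in endothelial cells, 48 higher and 13 lower (902 at an unadjusted p under 0.05). Without the animal labelled young 1 the count was 169. It was 37, 37, 31 and 40 without young 3, 4, 7 and 8. Without old animals 5 to 8 it was 16, and 8 of the 21 named called genes kept their calls, while Mgp (0.0864) and Gkn3 (0.13) lost theirs. Gkn3 also lost its call on summed UMIs.

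All 19 immediate early genes tested in endothelial cells had a positive change. Over all genes 3 rose, Fos, Junb and Ier2 (0.47), and adjusted over the list alone 12 rose (median log2 change 0.51, adjusted p = 3.55e-17, and adjusted p = 0.063 with an estimated correlation). Ier2 lost its call without any of young 2, 4 to 8 and old 1 to 4, 6 and 7 (0.0554 to 0.119). The immediate early genes were measured in dissociated cells, and a library series and age cannot be told apart. A difference in handling was therefore not separated from age for them. Heat shock genes were called higher (20 of 23 positive; 0 over all genes, 4 adjusted over the list alone; adjusted p = 8.41e-05, and adjusted p = 0.346 with an estimated correlation), and lost without old animals 1 and 2 (0.591). Blood-brain barrier genes were lower (19 of 23 negative, median -0.14; 2 over all genes, 6 adjusted over the list alone; adjusted p = 0.000137, and adjusted p = 0.125 with an estimated correlation). The 2 were Car4 (11.6 ± 2.94 to 7.72 ± 1.15, -0.55), a carbonic anhydrase, and Tfrc (1.90 ± 0.603 to 1.17 ± 0.267, -0.63), the transferrin receptor. Car4 was lost without any of young 3, 4, 5, 7 and 8 and old 1, 2, 3, 5 and 6 (0.0513 to 0.102), and Tfrc without any of young 3, 4 and 7 and old 1, 2, 6, 7 and 8 (0.0521 to 0.115).

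Nuclear genes of oxidative phosphorylation were lower in endothelial cells (70 of 77 negative, median -0.15, 0 called by either count; adjusted p = 1.14e-08, and adjusted p = 0.315 with an estimated correlation) and ribosomal protein genes higher (66 of 80 positive, median 0.12; 1 over all genes, Rpl6 at 0.81, and 2 adjusted over the list alone; adjusted p = 1.52e-07, and adjusted p = 0.432 with an estimated correlation). Rpl6 was lost without old animals 5 to 8 (0.458). Clock genes (11 of 16 positive; adjusted p = 0.0124, and adjusted p = 0.14 with an estimated correlation), lysosomal genes (22 of 29 negative; 0.0288, and adjusted p = 0.507 with an estimated correlation) and cholesterol synthesis genes (16 of 18 negative; 0.032, and adjusted p = 0.252 with an estimated correlation) had 0 called members by either count. The clock call was lost without young 5 (0.0609). The lysosomal call was lost without young 2 (0.0563), 4 (0.117) or 6 (0.095) or old 1 (0.0555), 2 (0.274) or both (0.535), and the cholesterol call without young 2 (0.0843), 4 (0.0821), 6 (0.0699) or 8 (0.0519) or old 2 (0.0541) or 6 (0.0695).

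Markers of other cells moved beside these groups in endothelial cells. Astrocyte genes were negative in 24 of 26 (median -0.36; 1 lower over all genes, and 11 lower and 1 higher adjusted over the list alone; adjusted p = 4.73e-09, and adjusted p = 0.252 with an estimated correlation). The called member was Cpe (11.0 ± 3.47 to 6.53 ± 1.37, -0.71), a carboxypeptidase also made by other cells, lost without young 6 (0.0522), 7 or 8 (up to 0.0638). All 7 oligodendrocyte precursor genes were negative (0 over all genes, 5 adjusted over the list alone; adjusted p = 5.5e-06, and adjusted p = 0.191 with an estimated correlation). Pericyte genes were positive in 13 of 16 (median 0.19, but 8 of 16 and 0.04 on summed UMIs) with 0 called (adjusted p = 0.032, and adjusted p = 0.499 with an estimated correlation), lost without young 2 (0.351), 5 (0.101) or 8 (0.0519) or old 5 (0.0776) or 7 (0.0566).

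In old oligodendrocyte precursors, Ube2c, which drives exit from mitosis, fell from 0.44 ± 0.188 to 0.029 ± 0.0771 CP10k (SD, n = 8 and 8; log2 change -2.13 ± 0.26, adjusted p = 5.97e-05), Top2a, a topoisomerase of dividing cells, from 0.338 ± 0.153 to 0.0611 ± 0.0986 (-1.56, 0.00425), and the chromatin protein gene Hmgb2 from 1.38 ± 0.264 to 0.64 ± 0.256 (-1.07, 0.00535). Ube2c was 0.220 CP10k in old animal 4 and at most 0.0127 in each of the other 7. The tubulin gene Tuba1b fell by 0.73 on the log2 scale and the histone gene H2afz by 0.64. C4b rose from 0.117 ± 0.106 to 0.44 ± 0.221 (1.34, 0.0112) and the protocadherin gene Pcdhb9 from 0.821 ± 0.314 to 1.59 ± 0.287 (0.93, 0.00535). All lay on the same side of the young mean in 8 of 8 old animals and passed with any 1 animal left out, but without old animals 5 to 8 they had adjusted p from 0.0506 (Ube2c) to 0.194 (Tuba1b). Hmgb2 and H2afz also lost their calls on means of the deposited log values.

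In all, 52 of 9663 genes passed in oligodendrocyte precursors, 16 higher and 36 lower (1217 at an unadjusted p under 0.05). The count was 66 without the animal labelled young 1, 33, 32, 32, 31, 26, 32 and 28 without young 2 to 8 in turn, and 29, 34, 31 and 33 without old 5 to 8 in turn. Without old animals 5 to 8 together it was 0 by limma. This type had 27 to 211 cells per animal.

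The list of neurogenesis and neuroblast genes, which includes genes of dividing cells, was called lower in oligodendrocyte precursors (10 of 17 negative; 5 lower over all genes, and 5 lower and 1 higher adjusted over the list alone; adjusted p = 0.00203, and adjusted p = 0.137 with an estimated correlation). The 5 were Ube2c, Top2a, Hmgb2, Cdk1 (-1.27) and Cenpf (-1.08), genes of the cell cycle or chromatin, and the last 2 were named after their values were seen. Ribosomal protein genes were lower (70 of 79 negative, median log2 change -0.19; 4 over all genes, 26 adjusted over the list alone; adjusted p = 1.58e-11, and adjusted p = 0.169 with an estimated correlation). The 4 were Rpl29 (5.30 ± 0.608 to 3.44 ± 0.839, -0.64), Rps7 (-0.59), Rps2 (-0.62) and Rps18 (-0.41, named after its value was seen). Rps7 was lost without any of young 2, 3, 6 and 8 and old 5 and 7 (0.0508 to 0.0636), and Rps2 without any of young 2, 3, 5 to 8 and old 5 to 8 (0.0505 to 0.0967).

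Nuclear genes of oxidative phosphorylation (68 of 77 negative, median -0.17; adjusted p = 1.6e-07, and adjusted p = 0.155 with an estimated correlation) and proteasome genes (28 of 34 negative, -0.20; 0.000645, and adjusted p = 0.443 with an estimated correlation) were lower in oligodendrocyte precursors with 0 called members by either count, and the proteasome call was lost without old animals 1 and 2 (0.0593). Clock genes were called higher (11 of 15 positive, 0 called by either count; adjusted p = 0.00273, and adjusted p = 0.0708 with an estimated correlation), lost without old animals 5 to 8 (0.105). Reactive astrocyte genes were called higher (6 of 8 positive, adjusted p = 0.00135, and adjusted p = 0.125 with an estimated correlation), lost without old animals 5 to 8 (0.073). Of these genes only C4b was called over all genes, and 2 were called adjusted over the list alone. Interferon response genes were called higher with 0 called members by either count (7 of 9 positive; adjusted p = 0.0315, and adjusted p = 0.443 with an estimated correlation). That call was lost without young 4 (0.0584), 5 (0.0611), 6 (0.0979), 7 (0.0512) or 8 (0.0519) or old 4 (0.103), 5 (0.136) or 6 (0.0874).

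In old astrocytes, the gene listed as PISD rose from 1.28 ± 0.814 to 3.04 ± 0.404 CP10k (SD, n = 8 and 8; log2 change 1.32 ± 0.17, adjusted p = 5.37e-05). Its symbol is in capitals, unlike the other mouse symbols here. It may therefore not be the gene of mitochondrial phosphatidylserine decarboxylase, and its identity was not tested. C4b rose from 0.638 ± 0.329 to 1.28 ± 0.30 (0.96, 0.00205) and the interferon-induced gene Ifi27 from 1.73 ± 0.266 to 2.61 ± 0.37 (0.57, 0.00263). Prpf4b, a kinase of the splicing machinery, rose from 0.697 ± 0.159 to 1.30 ± 0.444 (0.78, 0.0059). Kif5a, a kinesin motor best known in neurons, fell from 1.37 ± 0.319 to 0.842 ± 0.216 (-0.65, 0.0145). All lay on the same side of the young mean in 8 of 8 old animals and passed with any 1 animal left out. PISD and C4b were highest, among young animals, in the one labelled young 1. Without old animals 5 to 8 only PISD (0.0222) and Ifi27 (0.00814) of these passed.

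In all, 41 of 8574 genes passed in astrocytes, 26 higher and 15 lower (899 at an unadjusted p under 0.05). The share of higher genes was 63.4%, and 73.7% with values centred on the median gene. Without the animal labelled young 1 the count was 67. It was 24, 17, 26, 26, 13 and 17 without young 2 and 4 to 8 in turn, and 25, 19 and 18 without old 5, 7 and 8. Without old animals 5 to 8 together it was 3, and without old 1 and 2 it was 102.

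Nuclear genes of oxidative phosphorylation were lower in astrocytes (74 of 78 negative, median log2 change -0.12; 0 over all genes, 3 adjusted over the list alone; adjusted p = 1.52e-12, and adjusted p = 0.156 with an estimated correlation). Interferon response genes were higher (12 of 13 positive, median 0.26; 3 over all genes, 6 adjusted over the list alone; adjusted p = 6.21e-08, and adjusted p = 0.063 with an estimated correlation). The 3 were Ifi27, Bst2 (0.80) and Lgals3bp (0.45). Bst2 was lost without any of young 2, 4, 7 and 8 and old 3, 4, 7 and 8 (0.0536 to 0.0648), and Lgals3bp without any of young 4 to 7 and old 4, 6 and 8 (0.0503 to 0.0639). MHC class I genes were higher (9 of 11 positive; adjusted p = 0.00172, and adjusted p = 0.132 with an estimated correlation), with H2-D1 (0.48) called over all genes and 2 adjusted over the list alone, and the list was lost without old animals 5 to 8 (0.0791). H2-D1 was lost without any of young 2, 4 to 8 and old 4, 5, 6 and 8 (0.0542 to 0.0922). The reactive astrocyte list was called higher, with 3 of its 6 members positive and 3 higher adjusted over the list alone (adjusted p = 0.00146, and adjusted p = 0.154 with an estimated correlation). Its members called over all genes were C4b and H2-D1.

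Cholesterol synthesis genes were lower in astrocytes (21 of 23 negative; 0 over all genes, 4 adjusted over the list alone; adjusted p = 8.37e-05, and adjusted p = 0.285 with an estimated correlation). Ribosomal protein genes were called lower (64 of 79 negative; 3 lower and 1 higher adjusted over the list alone; adjusted p = 3.43e-05, and adjusted p = 0.47 with an estimated correlation), lost without old animals 5 to 8 (0.657), while Rpl6 alone rose over all genes (0.60). Rpl6 was lost without any of young 4, 7 and 8 and old 5, 7 and 8 (0.052 to 0.0648). Astrocyte homeostatic genes (24 of 26 negative, 0 called by either count; adjusted p = 0.00453, and adjusted p = 0.372 with an estimated correlation) were called lower, with a median of -0.07, and lost without old animals 5 to 8 (0.254). Long noncoding RNAs were called higher (7 of 9 positive; 0 over all genes, 2 adjusted over the list alone; adjusted p = 0.0145, and adjusted p = 0.125 with an estimated correlation).

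Mitochondrially encoded transcripts were called lower in astrocytes (9 of 13 negative; 5 lower and 1 higher adjusted over the list alone; adjusted p = 0.0159, and adjusted p = 0.522 with an estimated correlation), with mt-Nd1 (104 ± 8.6 to 80.9 ± 4.78, -0.36) called over all genes. With the animal number as a block the list had an adjusted p of 0.0709, and it was lost without young 1 (0.101) or 8 (0.107) or old 3 (0.0877), 4 (0.0704) or 6 (0.0699). The gene mt-Nd1 was lost without young 4, 7 or 8 or old 7 or 8 (0.0509 to 0.0655). Unfolded protein response genes were called higher (12 of 17 positive; 0 over all genes, 1 adjusted over the list alone; adjusted p = 0.0128, and adjusted p = 0.476 with an estimated correlation), lost without old 1 (0.124), 2 (0.158) or both (0.894).

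Markers of other cells moved in astrocytes too. Neuronal genes were negative in 15 of 20, with 1 lower over all genes (Stmn3, -0.52) and 5 adjusted over the list alone (adjusted p = 0.000804, and adjusted p = 0.293 with an estimated correlation). Stmn3 was lost without any of young 2 to 5, 7 and 8 and old 5 and 7 (0.0529 to 0.103). Microglial homeostatic genes were positive in 6 of 8, with 1 called by both counts, Mef2c (0.57), a transcription factor also used by neurons (adjusted p = 0.0308, and adjusted p = 0.155 with an estimated correlation). The list was lost without young 3 (0.0811), old 1 (0.123) or old 1 and 2 (0.187), and Mef2c without any of young 2 to 8 and old 1, 2, 3, 7 and 8 (0.0565 to 0.117).

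**Figure D3:**
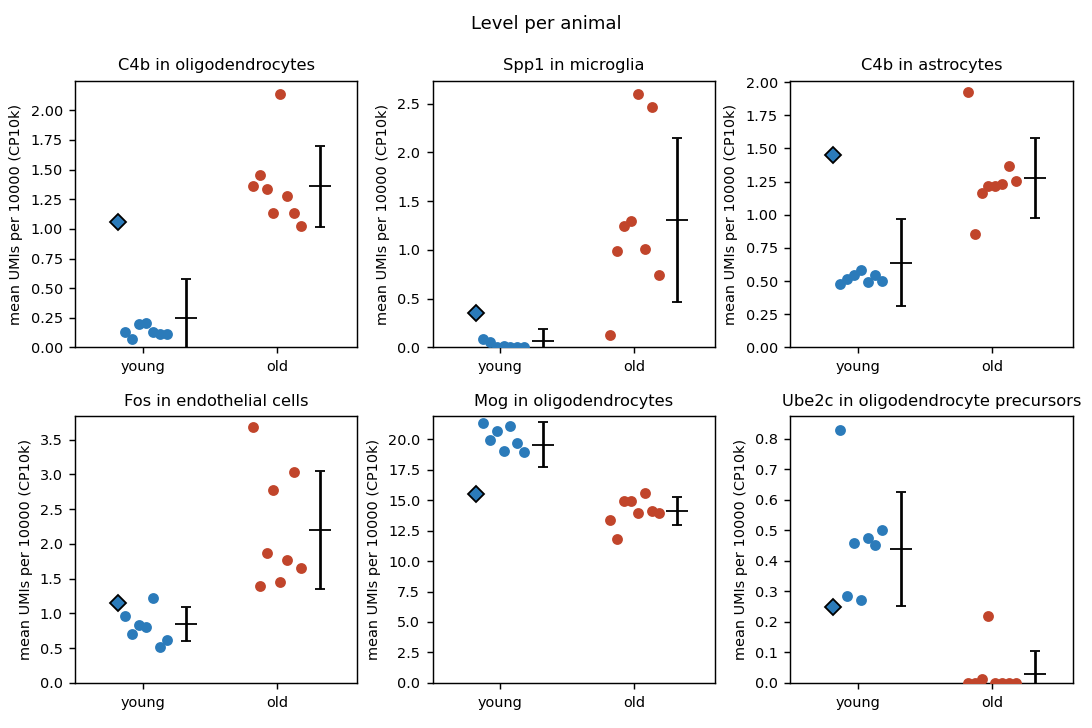
Level per animal (vertical axes, mean CP10k over the cells of the type) of C4b in oligodendrocytes and astrocytes, Spp1 in microglia, Fos in endothelial cells, Mog in oligodendrocytes and Ube2c in oligodendrocyte precursors, young in blue and old in red, with mean ± SD at the side (axes start at 0, where SD bars are cut off). The black-edged diamond is the animal labelled young 1, which had 1.06 CP10k of C4b in oligodendrocytes against a young mean of 0.252.

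In mature neurons a single gene of 9344 passed, PISD, with 3.29 ± 1.28 CP10k in young and 5.40 ± 0.607 in old animals (SD, n = 8 and 8; log2 change 0.76 ± 0.14, adjusted p = 0.0492, higher in 8 of 8; 984 genes at an unadjusted p under 0.05). It lost its call when any animal but young 1 or old 4 was left out (0.0617 to 0.234). Without the animal labelled young 1 the count was 24, without old 4 it was 3, and without any of the other 14 it was 0. Means of the deposited log values called 5 genes, 2 of them higher, and summed UMIs 7, 4 of them higher, against 1 of 1.

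Gene groups moved in mature neurons with few called members. Ribosomal protein genes were higher (74 of 79 positive, median log2 change 0.17; 0 over all genes, 3 adjusted over the list alone; adjusted p = 3.87e-16, and adjusted p = 0.345 with an estimated correlation) and mitochondrially encoded transcripts lower (10 of 13 negative, median -0.31; 0 and 7; adjusted p = 3.43e-05, and adjusted p = 0.26 with an estimated correlation). Nuclear genes of oxidative phosphorylation were called higher (62 of 76 positive, median 0.09, 0 called by either count; adjusted p = 8.41e-05, and adjusted p = 0.465 with an estimated correlation), lost without old animals 1 and 2 (0.23). Clock genes were called higher (14 of 18 positive; 0 over all genes, 1 adjusted over the list alone; adjusted p = 0.0151, and adjusted p = 0.169 with an estimated correlation), lost without young 5 (0.0507). Unfolded protein response genes were called higher (14 of 19 positive, 0 called by either count; adjusted p = 0.0385, and adjusted p = 0.465 with an estimated correlation), but their median was -0.02 on summed UMIs. That call was lost without young 1 (0.0788), 2 (0.222), 6 (0.084), 7 (0.0509) or 8 (0.0519) or old 1 (0.172), 2 (0.109) or both (0.622).

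Markers of other cells moved in opposite directions in mature neurons, with 0 called members by either count. All 20 astrocyte genes were negative (median -0.21; adjusted p = 8.41e-05, and adjusted p = 0.372 with an estimated correlation), and 11 of 12 myelin genes were positive (median 0.21; adjusted p = 0.00203, and adjusted p = 0.372 with an estimated correlation).

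Over all lists, 58 of the 153 pairs of list and type were called, 31 higher and 27 lower, and 25 of the 32 lists were called in at least 1 type. Of the 58, 55 kept their calls without the animal labelled young 1 (63 pairs called in all), 45 without old animals 5 to 8 and 45 without old animals 1 and 2. None of the 153 pairs was called by camera with an estimated correlation. When the 16 animals were split in other ways, the test with the preset correlation still called a median of 29 pairs (3 to 68). Many of these splits keep part of the age difference, but 1 that divided the old animals evenly, with 4 kept together, called 68. Single list calls are therefore less certain than their p-values state. Lists of glucocorticoid-induced (smallest adjusted p = 0.0908) and senescence genes (0.0974) were tested in all 6 types and called in none. Those of complement (0.776) and endothelial activation genes (0.0504) were tested only in microglia and endothelial cells and not called. That of border macrophages (0.954) was tested only in microglia and not called. Elsewhere these lists had fewer than 5 tested members. Complement as a list was thus not tested in oligodendrocytes, astrocytes and oligodendrocyte precursors, where C4b rose. Lists of choroid plexus and ependymal genes had fewer than 5 tested members in every type.

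Across the 6 types, 552 of 12378 genes were called in at least 1, and 7 were called higher in 3 or more, with 0 called lower in as many. Rpl6 and PISD were called in 4 types, and C4b, Prpf4b, Tspo, H2-D1 and Ogt in 3. C4b had log2 changes of 0.96 to 2.33 in the 3 types with enough of it. Tspo, a mitochondrial membrane protein, rose in oligodendrocytes (0.43), astrocytes (0.55) and microglia (0.40), and Ogt, the enzyme that adds N-acetylglucosamine to proteins, in oligodendrocytes (0.33), astrocytes (0.35) and oligodendrocyte precursors (0.54). Tspo was lost in microglia without any of young 2, 3, 5, 6 and 7 and old 1, 2, 7 and 8 (0.0505 to 0.0679). Ogt was lost without 10, 7 and 5 of the single animals in those 3 types, with adjusted p of at most 0.0833, 0.0905 and 0.0636. Prpf4b in oligodendrocyte precursors was lost without any of young 2 and 4 to 8 and old 1, 5, 7 and 8 (0.0523 to 0.096) and with neighbouring numbers treated as related (0.0567). PISD in microglia (0.47) was lost without young 5 or old 3, 5 or 8 (0.0508 to 0.0564). The mean change of Rpl6 over the 6 types was 0.33 in old animals 1 to 4 and 1.16 in old animals 5 to 8, against 0.75 in all. The number of shared genes was 19 without the animal labelled young 1. It was 3, 4, 2, 3, 3 and 4 without young 2 and 4 to 8 in turn, 4, 4 and 2 without old 5, 7 and 8, and 0 without old animals 5 to 8 together. With neighbouring numbers treated as related it was 2. Calls were then lost for Tspo in microglia (0.0594), H2-D1 in astrocytes (0.0779) and PISD in microglia (0.0572) and mature neurons (0.185). Ogt lost its calls in oligodendrocytes (0.0834) and astrocytes (0.0642). No separate test was made of the overlap between types, which share animals.

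Differences between types were tested directly. Ribosomal protein genes were shifted down in astrocytes (log2 difference from the other 5 types -0.20; exact permutation adjusted p = 0.0035, n = 8 and 8) and oligodendrocyte precursors (-0.33, 0.00599), and up in microglia (0.27, 0.0140) and oligodendrocytes (0.08, 0.0035). Their mean age change was negative in the first 2 types (-0.07 and -0.18) and positive in the last 2 (0.32 and 0.16). Mitochondrially encoded transcripts were shifted down in microglia (-0.31, 0.0035) and up in oligodendrocytes (0.21, 0.00874) and endothelial cells (0.11, 0.00599). Nuclear genes of oxidative phosphorylation were shifted down in oligodendrocyte precursors (-0.10, 0.0035) and astrocytes (-0.07, 0.0229) and up in microglia (0.10, 0.00599) and mature neurons (0.18, 0.0338). A shift up is relative to the other types and need not be a rise with age. The mean age change of oxidative phosphorylation genes was 0.01 in microglia and 0.08 in mature neurons. That of mitochondrially encoded transcripts was 0.13 in oligodendrocytes and 0.04 in endothelial cells. MHC class I genes were shifted up in microglia (0.18, 0.0114). Each of these 12 differences, of 30 tested, held in 8 of 8 old animals.

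Several of these differences were lost with fewer animals. In microglia the ribosomal difference and in oligodendrocytes the mitochondrial one had adjusted p of 0.139 and 0.135 without old animals 5 to 8. The oxidative phosphorylation difference in astrocytes was lost without young 3 (0.0563) or 7 (0.064), old 7 and 8 (0.0616) or old 5 to 8 (0.20), and that in mature neurons without old 1 and 2 together (0.134), young 2 (0.0676), 3 (0.0563), 4 (0.0642), 6 (0.0505) or 7 (0.0649) or old 1 (0.0633), 2 (0.0645) or 6 (0.0531). Without the animal labelled young 1 a further 3 passed, namely mitochondrial transcripts in mature neurons (-0.20, 0.0089), and oxidative phosphorylation (-0.13, 0.0370) and MHC class I genes (-0.32, 0.0148) in endothelial cells. Without old 5 the mitochondrial differences in oligodendrocyte precursors (0.22, 0.0186) and mature neurons (-0.18, 0.0466) passed. Others passed without young 8 (ribosomal in mature neurons, 0.16, 0.0420, mitochondrial in mature neurons, -0.18, 0.0473, and in oligodendrocyte precursors, 0.20, 0.0420), young 4 (mitochondrial in oligodendrocyte precursors, 0.20, 0.0360) or old 6 (the same, 0.20, 0.0420).

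**Figure D4:**
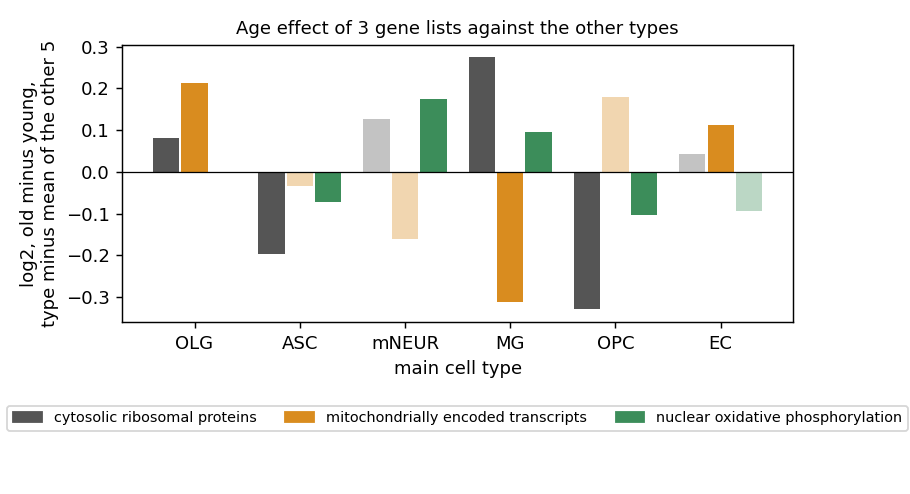
Age effect of 3 gene lists in each of 6 cell types minus the mean effect in the other 5 (vertical axis, log2, old minus young, n = 8 and 8). Full bars passed the exact permutation test and pale bars did not. Ribosomal protein genes span -0.33 (oligodendrocyte precursors, OPC) to 0.27 (microglia, MG).

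Gene by gene, 33 of the differences between 1 type and the other 5 passed, 31 of them in oligodendrocytes (7 more positive and 24 more negative there) and 2 in endothelial cells, over 5224 genes tested in each type. In the other 4 types limma called 0. The count of 33 was 365 with a pseudocount of 1, 598 on means of the deposited log values, 203 without a filter, 189 with a filter at 0.5 CP10k, 79 on summed UMIs and 93 with weights by cells. Fos changed more in endothelial cells than elsewhere (log2 difference 1.26, adjusted p = 0.00787). In oligodendrocytes Marcksl1 (-0.73, 0.00348), the chromatin protein gene Hmgn3 (-0.75, 0.00342), Igsf8 (-0.76, 0.00342), Ttyh1 (-0.65, 0.00367) and Hist1h1c (-0.95, 0.0374) changed more negatively, and Ndrg2 (0.69, 0.00413), abundant in astrocytes, more positively. The count was 143 without the animal labelled young 1, 19, 19, 19, 19 and 17 without young 3, 4, 5, 7 and 8, 20, 19 and 21 without old 3, 4 and 8, and 0 without old animals 5 to 8 together.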

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

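The comparisons of the 100 splits below were chosen after their result was seen; the other tests here were fixed beforehand. In 57 of 588 groups of animals tested (named genes, cell shares and depth), 1 animal lay far from its group by Dixon's test, where chance gives about 1 in 20. The animal labelled young 1 was the far one in 32 of the 57, old 2 in 9, and young 2 and old 5 in 4 each. The value given is the gap to the nearest animal over the range of the group.

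The animal labelled young 1 stood apart in oligodendrocytes for C4b (0.689), Rpl6 (0.685), Epdr1 (0.585), Tmem163 (0.815), Ttyh1 (0.611), Marcksl1 (0.712), Hmgn3 (0.77), Igsf8 (0.657), Mog (0.627) and Cldn11 (0.604), and in microglia for Spp1 (0.571), Crlf2 (0.542), Rpl6 (0.559), B2m (0.559), H2-K1 (0.55), Tnf (0.569), Srgn (0.604) and Vim (0.577). In astrocytes it did for PISD (0.622), C4b (0.833), Ddah2 (0.546) and Psmb8 (0.64), in endothelial cells for Ivns1abp (0.665), Sparc (0.687), Nnat (0.648) and UMIs per cell (0.566), in oligodendrocyte precursors for Rnd2 (0.533), Hn1 (0.62) and H2afz (0.538), and in mature neurons for PISD (0.544) and Clu (0.796). Its astrocyte share also did (0.595).

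Old 2 stood apart for H2-D1 (0.563) and Bhlhe41 (0.644) in oligodendrocytes, Fcrls (0.545) in microglia, Hspa1b (0.565) in endothelial cells, Cldn11 (0.673) in mature neurons, and Ankrd12 (0.639), Rnd2 (0.745), Hn1 (0.652) and Clock (0.618) in oligodendrocyte precursors. Old 5 did for C4b in oligodendrocytes (0.529), Rps2 in astrocytes (0.633), Slc38a5 in endothelial cells (0.563) and Pld1 in microglia (0.605). Young 2 did for Uqcrh in astrocytes (0.54), H2-D1 in endothelial cells (0.58), PISD in microglia (0.588) and the monocyte share (0.773), and old 1 for Spp1 in microglia (0.53) and the monocyte share (0.58). Others were young 8 for S100a1 (0.567) and Mt3 (0.607) in microglia, old 8 for Nell2 in olfactory ensheathing glia (0.571), old 4 for Ube2c in oligodendrocyte precursors (0.897), young 4 for the share of hemoglobin-expressing vascular cells (0.653) and young 3 for that of macrophages (0.543).

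Age effects that differed between cell types by a test of the difference were those of ribosomal protein genes in oligodendrocytes (0.081), astrocytes (-0.197), microglia (0.274) and oligodendrocyte precursors (-0.329), of mitochondrially encoded transcripts in oligodendrocytes (0.212), microglia (-0.312) and endothelial cells (0.113), of oxidative phosphorylation genes in astrocytes (-0.071), mature neurons (0.175), microglia (0.0957) and oligodendrocyte precursors (-0.103), and of MHC class I genes in microglia (0.183). Single genes were Fos in endothelial cells (1.26) and, in oligodendrocytes, Hist1h1c (-0.947), Ttyh1 (-0.65), Marcksl1 (-0.73), Hmgn3 (-0.752), Igsf8 (-0.757) and Ndrg2 (0.693).

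The splits took the animals as independent, although neighbouring numbers deviated together (mean r 0.255 in oligodendrocytes and 0.229 in microglia), and splits that keep neighbours together were not run, so chance is excluded here only for independent animals. On that condition, among 100 splits, the real one included, chance could be excluded at 5% for the genes called in oligodendrocytes (363, with 2 splits calling as many and 660 in the highest other), astrocytes (41, 2, 61), microglia (63, 2, 214), oligodendrocyte precursors (52, 2, 96) and endothelial cells (61, 3, 134), and in olfactory ensheathing glia (14, 1, 2) and pericytes (4, 3, 30). It could also be excluded for genes shared by 3 or more types (7, 2, 34) and gene differences between types (33, 3, 93). For lists the values were 58, 4 and 68. A split that divided the old animals evenly, with 4 kept together, called 68 list pairs, so no conclusion is drawn for lists. Chance could not be excluded for mature neurons (1, with 6 splits calling as many and 53 in the highest other). These comparisons were not adjusted for their number. The highest split in oligodendrocytes exchanged young 1 for old 4, and a split that calls many more genes than the labels points to a structure of the samples.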

How the results depend on the processing

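The neighbouring-number analyses, the omissions of several old animals and the single omissions were chosen after the data were seen; all other settings were planned. Counts of genes, list pairs, shares and differences that moved by over 1.5 times are given here, and the cause of these moves was not tested. The medians of 2 called lists turned negative, red blood cell genes in oligodendrocytes on means of the deposited log values (-0.0045) and unfolded protein response genes in mature neurons on summed UMIs (-0.02). No called gene named by the rule, and no called share or list difference, was reversed. Of the comparisons of named genes, lists, shares, depth and list differences, the planned settings left 2876 as they were. In these settings 264 lost and 64 gained a call, and in the added ones the numbers were 6680, 773 and 114. Types with few cells, such as pericytes (a median of 47 cells per animal) and olfactory ensheathing glia (52.5), had the lowest recovery in simulated data.

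A pseudocount of 1 gave 0 genes in mature neurons and 365 gene differences between types. A pseudocount of 0.02 gave 1 gene in olfactory ensheathing glia, 33 in oligodendrocyte precursors, 1 in pericytes and 0 in mature neurons. No filter gave 10 in astrocytes, 21 in endothelial cells, 35 in microglia, 0 in olfactory ensheathing glia, pericytes and mature neurons, 2 shared genes and 203 differences. A filter at 0.5 CP10k gave 21 in astrocytes and in oligodendrocyte precursors, 6 in olfactory ensheathing glia, 1 in pericytes, 0 in mature neurons and 189 differences. With at least 50 cells, olfactory ensheathing glia had 2 and pericytes 26. Means of the deposited log values gave 23 in astrocytes, 241 in oligodendrocytes, 11 in pericytes, 5 in mature neurons and 598 differences. Summed UMIs gave 689 in oligodendrocytes, 7 in mature neurons and 79 differences. Weights by cells gave 81 in astrocytes, 109 in endothelial cells, 130 in microglia, 114 in oligodendrocyte precursors, 33 in pericytes, 0 in mature neurons and 93 differences. Genes per cell as a covariate gave 7 in olfactory ensheathing glia, 7 in pericytes and 2 in mature neurons.

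The animal numbers do not pair the samples: r between same-numbered animals ran from -0.243 to 0.284 in mature neurons, and 3 of 8 pairs exceeded 0.1 in oligodendrocytes. With the number as a block, endothelial cells had 99 genes, olfactory ensheathing glia 24 and pericytes 17. Exact sign flips within numbers (256 flips) gave 0 shares and 0 list differences. By sign flips the called shares had an adjusted p of 0.0651 and the called list differences 0.0521 to 0.108. Means of neighbouring numbers also gave 0 and 0, in a design that can hardly pass (smallest p of 4 against 4 animals 0.0286). Neighbouring numbers as a random effect gave 16 genes in astrocytes, 40 in endothelial cells, 39 in microglia, 169 in oligodendrocytes, 32 in oligodendrocyte precursors, 0 in mature neurons and 2 shared genes. Centred log ratios gave 6 shares, losing oligodendrocyte precursors (0.245) and gaining endothelial cells (0.0453), the type annotated EPC (0.033), oligodendrocytes (0.0389) and vascular smooth muscle cells (0.033). A pseudocount of 1 added the interferon response difference in astrocytes (0.12, adjusted p = 0.0265), which rests on only 2 members of the list. Camera with an estimated correlation gave 0 list pairs.

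Without old animals 7 and 8 the counts were 5 in astrocytes, 34 in microglia, 9 in olfactory ensheathing glia, 22 in oligodendrocyte precursors, 0 in mature neurons, 1 shared gene, 15 differences and 2 depth comparisons. Without old 5 to 8 they were 3 in astrocytes, 16 in endothelial cells, 11 in microglia, 0 in olfactory ensheathing glia, 114 in oligodendrocytes, 0 in oligodendrocyte precursors, 9 in pericytes, 0 in mature neurons, 0 shared genes, 0 differences, 5 shares (macrophages and vascular smooth muscle cells gained, 0.0253 each) and 3 depth comparisons, and the mitochondrial difference in oligodendrocyte precursors passed (0.25, 0.0424). Without old 1 and 2 they were 102 in astrocytes and 0 in pericytes.

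Leaving out each animal in turn gave 228 to 662 genes in oligodendrocytes (lowest without young 4, highest without young 1), 13 to 67 in astrocytes (young 7, young 1), 0 to 24 in mature neurons, 32 to 199 in microglia (young 7, young 1), 26 to 69 in oligodendrocyte precursors (lowest without young 6), 31 to 169 in endothelial cells (young 7, young 1), 5 to 20 in olfactory ensheathing glia (lowest without young 5) and 1 to 20 in pericytes (old 2, young 1). Shared genes ran from 2 to 19, differences from 17 to 143, list pairs from 52 to 64, list differences from 10 to 15, shares from 3 to 5 and depth comparisons from 0 to 0.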

Other observations

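The tests of a batch and of depth in young 1, of fewer astrocytes, and of Rpl6 and the other shared genes were chosen after the results were seen. In olfactory ensheathing glia, which accompany the olfactory nerve, 14 of 7880 genes passed between 6 young and 8 old animals with enough cells, 10 higher and 4 lower (652 at an unadjusted p under 0.05). Rpl6 rose from 1.04 ± 0.358 to 2.59 ± 1.01 CP10k (log2 change 1.21 ± 0.21, adjusted p = 0.00246) and the secreted protein gene Nell2 fell from 1.68 ± 0.365 to 0.711 ± 0.245 (-1.19 ± 0.23, 0.00779), each in 8 of 8 old animals. PISD rose by 1.11 (0.0147, lost without young 7) and Sh3bgr fell by 0.92 (0.0231, lost without young 5 or 6). The count was 8, 5 and 8 without young 3, 5 and 7, and 9 and 8 without old 3 and 8.

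In pericytes, which wrap the capillaries, 4 of 8783 genes passed, 1 higher and 3 lower (646 at an unadjusted p under 0.05). Clu, which encodes the secreted chaperone clusterin, fell from 6.39 ± 2.69 to 2.75 ± 1.03 CP10k (-1.12 ± 0.22, adjusted p = 0.011, 8 of 8), and the linker histone gene H1f0 from 3.66 ± 1.32 to 1.76 ± 0.692 (-1.03 ± 0.20, 0.011, 8 of 8). Cpe fell from 10.9 ± 3.72 to 6.14 ± 2.03 (-0.80 ± 0.17, 0.0265, 7 of 8). Cpe is also a member of the list of astrocyte genes and was called lower in endothelial cells. Free astrocyte RNA was not tested in pericytes, for Cpe or the other genes. The gene model 8430408G22Rik, chosen after its value was seen, rose by 1.44 (0.0076). Clu was lost without young 7 or 8 or old 2 or 8, H1f0 without young 6 or old 2, and Cpe without young 6 to 8 or old 2 or 8 (0.0509 to 0.145). The count was 20, 7, 10, 12, 2, 2 and 2 without young 1, 2, 3, 5, 6, 7 and 8, and 1, 8, 7, 10, 9 and 2 without old 2, 4, 5, 6, 7 and 8.

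The animal labelled young 1 lay with the old animals. Its positions in mature neurons and oligodendrocyte precursors, not looked at before the test, were both above those of the other 7 young animals (lower of the 2, 0.601), and its shares of 3 types (immature neurons, neuronal-restricted precursors and oligodendrocyte precursors) lay nearer to the old mean, so a wrong age label or an older animal is a candidate explanation. Its share of neuronal-restricted precursors (0.219%) also lay within the other young animals (0.159% to 0.647%). Its astrocyte share (9.12%) lay below every old animal (12.8% to 19.1%) and every other young animal (18.9% to 25.5%). Its shares thus did not match the old animals throughout. A batch shared with young 2 as the whole cause was argued against by the position of that animal in oligodendrocytes (-0.0751), although it was the highest of the other young animals in astrocytes (0.329), microglia (0.341) and oligodendrocyte precursors (0.173). Depth was argued against by 2833.5 UMIs per cell, within the 2344 to 3094 of the other young animals, except that in endothelial cells its UMIs per cell lay far from theirs (0.566 by Dixon's test). An exchange with old 4 was not tested: that animal lay within the young range in mature neurons (0.332), above it in oligodendrocyte precursors (0.366) and astrocytes (0.49), and far above it in oligodendrocytes (0.756), microglia (0.678) and endothelial cells (0.778). Records of the animals or a genotype would test the labels, and an unusual young brain stays open as untested.

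Rpl6, called in 4 types, had a mean log2 change of 0.33 in old animals 1 to 4 and 1.16 in old animals 5 to 8, so a library series may account for part of its rise. The other 6 shared genes had a median of 0.375 in old animals 1 to 4 against 0.47 in all. That argues only against old libraries 5 to 8 as their whole cause as a set. Prpf4b (0.34 against 0.52) and Ogt (0.11 against 0.21) kept less, so libraries 5 to 8 stay open for them. Without old animals 5 to 8, limma called 0 genes in 3 types. Old animals 1 to 4 also carry higher cell-name numbers (33 to 38) than every young animal (6 to 28). A series that runs with age therefore stays open for all the shared genes. Age and reads shared with Rpl6 pseudogenes stay open as untested, and libraries of both ages made together would test the series.

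Astrocyte genes were lower in old microglia and endothelial cells. Across the 16 animals the deviations of the 22 and 26 genes from the age means went together (r = 0.662, permutation p = 0.00577; rho = 0.659, p = 0.00691; r = 0.546 without young 8 and young 1), so free astrocyte RNA in the droplets is a candidate explanation. These p-values took the animals as independent, although neighbouring numbers deviated together (mean r 0.229 in microglia and 0.0813 in endothelial cells). The level of the astrocyte genes as a percentage of that in astrocytes went from 4.97 ± 1.31 to 3.78 ± 0.322 in microglia and from 18.6 ± 3.43 to 15.6 ± 2.44 in endothelial cells, and from 6.51 to 5.87 in mature neurons, but from 8.68 to 8.92 in oligodendrocytes and 12.8 to 13.9 in oligodendrocyte precursors. Fewer astrocytes in the sample, with a difference in share of -4.12 points (exact permutation adjusted p = 0.218, 8 of 8), could neither be shown nor excluded as the reason. That outcome rests on the animal labelled young 1: without it the difference was -5.68 points (exact permutation adjusted p = 0.0140). Age itself stays open as untested, and empty droplets, not analysed here, would test the free RNA.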
